A study of Homo sapiens with 13 samples.

How the data were processed

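RNA-seq was done on 13 samples of DLD-1 cells in 3 experiments, as siCtrl, siSOX9 and 2 siRNAs against Y14. Per the labels' protocols, cells were harvested 72 h after transfection with 50 nM of siRNA, RNA was treated with DNase, and stranded libraries were made from polyadenylated transcripts. Per the submitters' processing notes, TopHat2, Bowtie, HISAT2, SAMtools, HTSeq and DESeq were used with the genome build hg19. Their versions, order and settings were not given in the sources used here. Whether reads were counted by strand was not given in the sources used here.

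The authors deposited 2 comparison tables, and both were used. Per the file headers, each holds for every gene symbol a mean over all libraries and a mean per arm. These means are a signal, namely read counts divided by a size factor per library, as the deposited tables name them. Per the file headers the tables also hold a fold change, which is the ratio of the arm means, its log2 value, a p-value and an adjusted p-value. The authors' adjusted p-values equalled Benjamini-Hochberg values over all genes with reads. From the share of each arm in the overall mean, 4 of 7 libraries in the siSOX9 table and 4 of 6 in the siY14 table belonged to the treated arm. No column carried a single library, and 0 columns of per-sample values were left unused. Of 23886 listed symbols, 18747 had reads in the siSOX9 table and 17706 in the siY14 table. Mitochondrially encoded genes were not listed. RBM8A, the Y14 gene, was listed at 0 in both deposited tables, so it was not analysed here.

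Groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. That plan assumed counts per library, separate arms for both Y14 siRNAs and an experiment term. The deposited tables hold none of these, so the main values are the fold changes and adjusted p-values of the authors' deposited tables, with an adjusted p of 0.05 as threshold. Results for each Y14 siRNA and for each experiment were not made. All else described from here on was chosen after the deposited tables were seen.

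The deposited arm means carry 15 significant digits. Each mean is a sum of whole reads, weighted by 1 over the size factor and the number of libraries. The value of 1 read in each library was found from the lowest means shared by many genes. A set of whole reads was accepted for a gene where it gave the printed mean and was far likelier than any other. Whole reads came out in both arms for 13027 genes (69.5% of those with reads) of the siSOX9 table and 11558 (65.3%) of the siY14 table. Tested on simulated data, 1 of 2400 sets per table was wrong. Of arm means up to 600 that were shifted away from a whole-read sum, 0 of 1500 per table were accepted. That figure does not cover recovered genes with higher means. Recovered libraries have no sample name, and their letters order them by depth. Estimated depth ran from 24.8 to 184 M counts in the siSOX9 table and from 49.5 to 71.6 M in the siY14 table. Genes with high means were recovered less often, since more sets of reads fit them and the highest means were not tried. Sets were judged likelier the closer they lay to equal normalised counts within an arm. Above an arm mean of 600, sets with a wide spread were refused. Standard deviations and errors of recovered genes with high means can therefore be too small.

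Recovered counts of genes with a mean of at least 10 were tested with limma 3.58.1 (voom) in R 4.3.3, with library sizes set by the authors' size factors and Benjamini-Hochberg adjustment. The difference between the knockdowns used a joint limma-voom model of both tables. Tested on simulated data with known changes, the siSOX9 design recovered 96 of 97 genes changed 2-fold and 103 of 103 changed 4-fold, with 12 false calls among 211. The siY14 design recovered 95 of 99 and 101 of 101, with 8 false calls among 204. The simulated libraries were independent, whereas the siY14 libraries formed pairs. Standard deviations and errors come from these recovered counts, while fold changes without them come from the authors' deposited tables.

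Gene lists covered Wnt/beta-catenin, Notch, p53, YAP/TEAD and SOX9 cartilage targets, SOX family genes, and stem, enterocyte, goblet, epithelial and mesenchymal markers. They also covered S phase, G2/M, integrated stress, unfolded protein, interferon, NF-kappaB, hypoxia and cholesterol genes. RNA lists held the exon junction complex, nonsense-mediated decay factors and substrates, SR proteins, hnRNPs and cytosolic ribosomal proteins. Mitochondrially encoded genes and markers of immune, fibroblast and endothelial cells completed the 28 lists, of which 25 had at least 5 measured members. They were tested with limma's cameraPR, with a preset correlation of 0.01, on the signed normal score of the authors' p-value. Members counted as higher or lower passed the authors' adjusted p of 0.05, and a second count was adjusted over the list alone. In 100 simulated draws on 13649 genes of the siSOX9 table, 99.3% of shifted lists and 1% of others were called. For siSOX9 the median and the test of S phase, enterocyte and hypoxia genes differed in sign, and for siY14 those of Wnt targets, none of them past the test.

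Named genes were the target, the 10 largest increases and decreases with a mean of at least 5 CPM and treated libraries beyond the control libraries, up to 4 members of a list past its test and up to 2 of any other. For both knockdowns together they were 10 genes called in both, by the smaller change and without the 5 CPM minimum, and 5 genes per direction of the difference. A few items that this rule names are not reported here.

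Length, GC content and exon number came from the GENCODE v29 transcripts, matched by symbol, for 98.0% of genes called with siSOX9 and 97.8% of those called with siY14. That annotation is of another genome build than hg19, so no coordinates are given. Expected overlaps were also drawn from 10000 permutations within 10 bins of mean count. Alternatives were no filter on low counts, a 2-fold minimum, each library left out in turn, TMM and RLE factors from the recovered genes, limma on log2 normalised counts with pseudocounts of 0.1, 1 and 10, depth class as a term, no deepest libraries, a GC and length trend removed, other scaling of the arms and other list tests. Equal totals in both arms would shift log2 fold changes by 0.01 for siSOX9 and 0.07 for siY14. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Exon-level and splicing data were not analysed here.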

Results

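Polyadenylated RNA was sequenced from DLD-1 cells, an established line of human colon tumour cells, 72 h after transfection with 50 nM of small interfering RNA (siRNA). The 13 samples came from 3 experiments. Experiment 1 held 2 samples with a control siRNA (siCtrl) and 3 with an siRNA against SOX9 (siSOX9), and experiment 2 held 1 sample of each. Experiment 3 held 2 siCtrl samples and 2 samples with each of 2 siRNAs against Y14, numbered 9 and 10. SOX9 is a transcription factor of the intestinal crypt base. Y14, the product of RBM8A, is a core protein of the exon junction complex, which is deposited on mRNA at splicing and takes part in nonsense-mediated decay. The title of the series names a question about SOX9 in transcription and in alternative splicing, and gene-level values bear on the first of these.

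The deposited values were 2 comparison tables with a mean normalised read count per arm for each of 23886 gene symbols. The first set 4 siSOX9 samples against 3 siCtrl samples of experiments 1 and 2. The second set the 4 siY14 samples, with both siRNAs pooled, against the 2 siCtrl samples of experiment 3. Reads per library were recovered from the arm means for 13027 genes of the siSOX9 table and 11558 of the siY14 table. The recovered libraries carry no sample name, and they are lettered from a, the deepest of an arm. Estimated depth in the siSOX9 table was 179, 38.1 and 25.0 M counts for siCtrl libraries a to c, and 184, 41.7, 30.6 and 24.8 M for siSOX9 libraries a to d. In the siY14 table it was 67.1 and 47.2 M counts for siCtrl libraries a and b, and 71.6, 70.4, 51.4 and 49.5 M for siY14 libraries a to d. The labels do not say that samples were separate cultures, so every p-value of a single gene measures only the spread between these samples, which may be technical. The cameraPR and overlap tests take genes as their units instead.

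The first comparison asked which transcripts changed when SOX9 was reduced. SOX9 itself fell from a mean normalised count of 24468 with siCtrl to 9067 with siSOX9 in the authors' deposited table, a log2 fold change of -1.43 with an adjusted p of 1.40e-04. PROX1, a homeobox transcription factor and a target of Wnt signalling in colon tumours, fell from 814 ± 28.9 (SD, n = 3) to 168 ± 20.9 (SD, n = 4) normalised counts in the recovered libraries. DACT1, which encodes a regulator of the Wnt pathway protein Dishevelled, rose from 55.4 ± 11.4 (SD, n = 3) to 536 ± 43.5 (SD, n = 4). WNT5A, a secreted Wnt ligand of the non-canonical branch, rose from 145 ± 14.0 (SD, n = 3) to 620.3 ± 51.5 (SD, n = 4). TRIB3, a pseudokinase induced by the integrated stress response, fell from 17923 to 4698 in the authors' deposited table, with an adjusted p of 7.33e-23.

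Among the other large increases, LAMA2, a laminin chain of the basement membrane, had a log2 fold change of 1.88 in the authors' deposited table, and SAMD11 had 2.23. SP5, a transcription factor induced by Wnt signalling, rose by 1.56 and SESN3, a sestrin that restrains mTORC1 signalling, by 1.54 on the log2 scale in the authors' deposited table. OSGIN1, an oxidative stress response gene, had 1.49, TEX14 had 1.46, the histone gene HIST1H2BK had 1.45 and DOCK4, an exchange factor for RAC GTPases, had 1.43 in the authors' deposited table. Histone genes share reads with near-identical copies, so the HIST1H2BK value is uncertain. Among the decreases, S100P, a calcium-binding protein, had -1.84, FGFRL1, a receptor of the fibroblast growth factor receptor family, had -1.77 and FGD2, an exchange factor for CDC42, had -1.77 in the authors' deposited table. ATP13A2, a lysosomal polyamine transporter, had -1.72, ANKRD27, an endosomal trafficking protein, had -1.63 and C6orf15 had -1.60 in the authors' deposited table. MACC1, a gene linked to metastasis of colon cancer, had -1.59 and SPNS2, a transporter of sphingosine-1-phosphate, had -1.55 in the authors' deposited table. The rule for naming asked for siSOX9 libraries beyond the siCtrl libraries, which could not be checked for OSGIN1, HIST1H2BK, DOCK4 and TRIB3, whose reads per library were not recovered. For ANKRD27, 1 siSOX9 library stood well above the others.

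**Figure D1:**
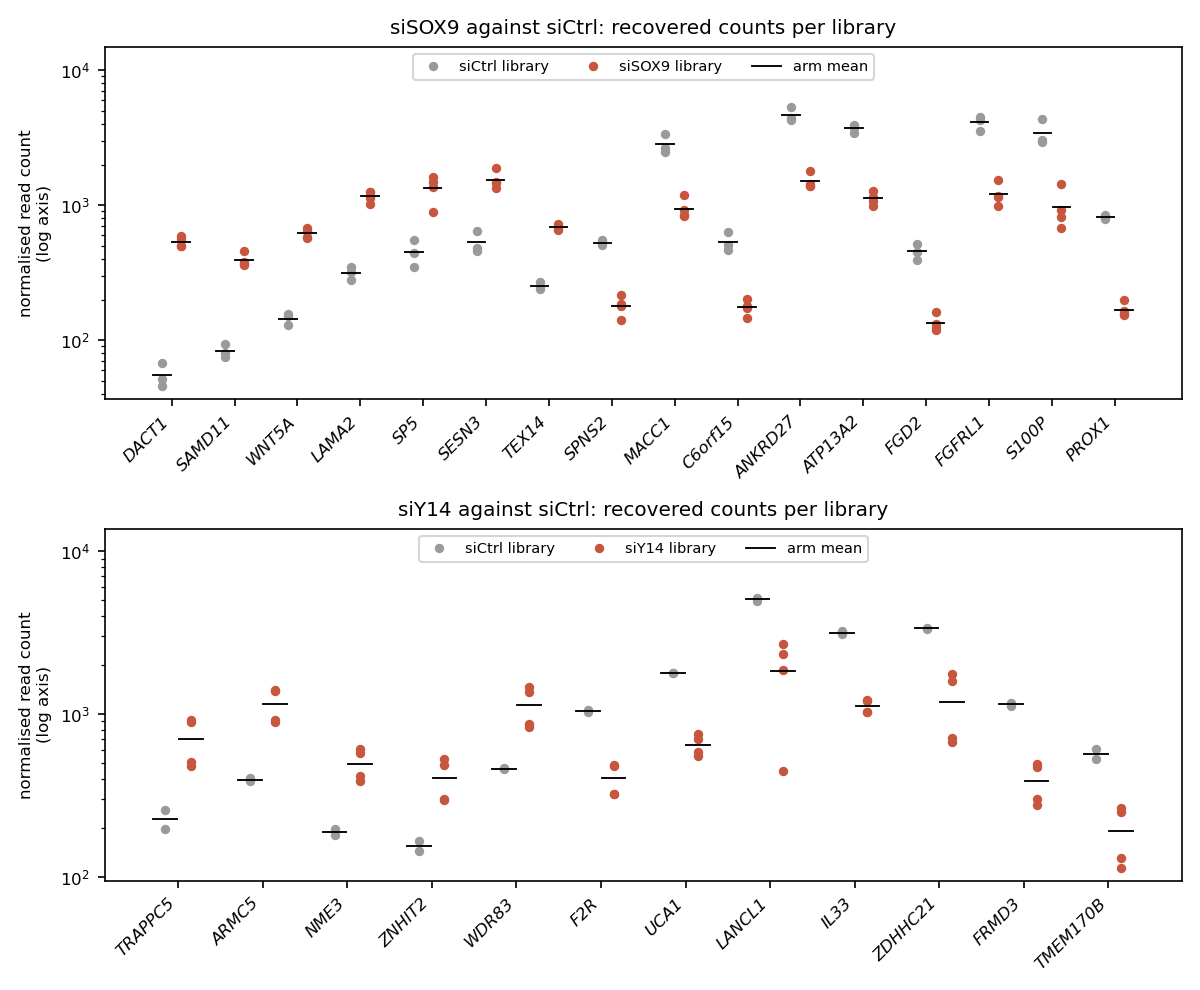
Normalised read counts (log axis) of named genes with the largest changes whose reads were recovered, with 1 point per library and a line at the arm mean, for siSOX9 (top) and siY14 (bottom) against siCtrl. PROX1 lay between 153 and 199 in the siSOX9 libraries and between 788 and 845 in the siCtrl libraries, while LANCL1 ranged from 443 to 2678 over the 4 siY14 libraries.

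In all, 650 of 18747 genes with reads passed an adjusted p of 0.05 in the authors' deposited table, 224 higher and 426 lower with siSOX9. A change of at least 2-fold was reached by 265 of them in the authors' deposited table, 116 higher and 149 lower. Reads were recovered for 483 of the 650 genes, and in 481 of these the siSOX9 and siCtrl libraries did not overlap. The same separation was found in 28.8% of all recovered genes with a mean of at least 10, and chance gives it in 5.71%. A limma-voom test of the recovered counts called 1414 of 7929 genes, 598 higher and 816 lower. All 473 of the authors' calls that it tested were called again in the same direction. With a trend in GC content and length removed the balance turned, to 942 higher and 870 lower. Without siCtrl library a, 333 were higher and 675 lower.

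Of 25 gene lists tested, 4 passed the limma list test (cameraPR) for siSOX9, all lower. Integrated stress response genes, which encode amino acid synthesis enzymes, transporters and regulators induced by ATF4, were lower with an adjusted p of 4.72e-06 in that test. Of their 24 measured members 1 rose and 4 fell, and 1 rose and 9 fell when adjusted over the list alone. Beside TRIB3, PHGDH and PSAT1, enzymes of serine synthesis, fell by 0.81 and 1.17 on the log2 scale in the authors' deposited table. CTH, which makes cysteine, rose by 0.88 in the authors' deposited table. Reads were recovered for 7 members, and TRIB3, PHGDH and PSAT1 were not among them. On those 7 members limma's camera gave the list an adjusted p = 0.894 with an estimated correlation, and 0.855 with the preset one. Goblet and secretory markers were lower with an adjusted p of 3.37e-05 in cameraPR, with 1 of 15 members higher and 5 lower, and 1 higher and 6 lower when adjusted over the list alone. The mucosal peptide TFF1 fell by 1.30, the Notch ligand DLL4 by 1.35 and the transcription factor KLF4 by 0.90 on the log2 scale in the authors' deposited table. CREB3L1, a membrane-bound transcription factor of secretory cells, fell by 2.46 in the authors' deposited table, and 1 siSOX9 library stood well above the others for this gene. On 13 members with recovered reads, camera gave the list an adjusted p = 0.159 with an estimated correlation, and 0.00393 with the preset one. With a trend in GC content and length removed, cameraPR gave an adjusted p of 2.09e-05 for this list.

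Intestinal stem and progenitor markers were lower with an adjusted p of 0.0279 in cameraPR, and 2 of 16 members fell, or 5 when adjusted over the list alone. The telomerase subunit TERT fell by 1.44 and the ephrin receptor EPHB2 by 0.59 on the log2 scale in the authors' deposited table. PROM1 and the Wnt-induced factor ASCL2 had log2 fold changes of -1.83 and -1.01 in the authors' deposited table, with adjusted p of 0.105 and 0.115. The list had an adjusted p = 0.436 with an estimated correlation in camera, over 8 members, and 0.229 with the preset one. Epithelial junction and keratin genes had an adjusted p of 0.0279 in cameraPR, with 1 of 25 members higher and 2 lower, and the same counts when adjusted over the list alone. The keratin KRT7 fell by 1.37 and the epithelial transcription factor ELF3 by 0.60 on the log2 scale, while the tight junction claudin CLDN2 rose by 1.20, all in the authors' deposited table. TJP3 had a log2 fold change of -0.51 and an adjusted p of 0.184 in the authors' deposited table. The list had an adjusted p = 0.159 with an estimated correlation in camera, over 7 members, and 0.00393 with the preset one. With a trend in GC content and length removed, cameraPR gave an adjusted p of 0.0681 for both the stem and the epithelial list, and its rank form gave 0.211 for the stem list.

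The other 21 lists had adjusted p of 0.224 to 0.891 for siSOX9 in cameraPR, and counts adjusted over the list alone are given where they differ. Of 24 Wnt/beta-catenin targets 2 rose and 3 fell, or 3 and 6 when adjusted over the list alone, with APCDD1 at 1.43 on the log2 scale in the authors' deposited table. Of 7 SOX family genes SOX13 rose by 1.06 in the authors' deposited table, and SOX9 was the member that fell, or 1 rose and 2 fell when adjusted over the list alone. Of 16 enterocyte and colonocyte markers 2 rose and 2 fell, or 3 and 2 when adjusted over the list alone, with VIL1, which encodes villin of the brush border, at -1.19 and CEACAM5 at -2.02 in the authors' deposited table. Of 9 Notch targets 2 fell, LFNG by 1.04 and NOTCH1 by 0.69 on the log2 scale in the authors' deposited table. Of 26 p53 targets 2 fell, or 1 rose and 2 fell when adjusted over the list alone, the cytokine gene GDF15 by 1.43 and the death receptor gene TNFRSF10B by 0.62 in the authors' deposited table. Of 21 hypoxia and glycolysis genes 2 fell, or 1 rose and 5 fell when adjusted over the list alone, with VEGFA falling by 0.71 and MXI1 by 0.79 in the authors' deposited table. Of 24 cholesterol synthesis genes 2 rose and 1 fell in the authors' deposited table, with INSIG1 at 0.79. The cytokine gene IL1B rose by 3.30, the only called gene of 18 NF-kappaB and inflammatory genes in the authors' deposited table, where 1 rose and 2 fell when adjusted over the list alone. IL1B was low with siCtrl, at 4.75 normalised counts against 46.8 with siSOX9. SAMD9 was the called gene of 31 interferon-stimulated genes and RRM2 of 33 S phase genes, at 0.82 and 0.68 in the authors' deposited table. ANKRD1 was the called gene of 19 YAP/TEAD targets and PCBP1 of 34 hnRNP genes, at -0.95 and -0.53 in the authors' deposited table.

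None of 37 G2/M genes, 18 unfolded protein response genes, 16 mesenchymal genes, 6 cartilage genes or 47 cytosolic ribosomal protein genes passed for siSOX9 in the authors' deposited table. Neither did any of 14 exon junction complex genes, 14 nonsense-mediated decay factors, 30 nonsense-mediated decay substrates or 14 SR protein genes in the authors' deposited table. Among markers of other cell types, 0 of 4 measured immune markers passed, and of 3 fibroblast and endothelial markers COL1A1 rose by 1.28 and PDGFRB fell by 0.88 in the authors' deposited table. Adjusted over the list alone, 1 cartilage gene fell, and 2 mesenchymal genes rose and 2 fell. The lists of other cell types had too few measured members for the list test. The deepest siCtrl library and the deepest siSOX9 library, each over 4 times deeper than the next, deviated from their arm means together, with a correlation of 0.88 across 5770 genes. Without both, limma-voom called 2298 genes, and with depth class as a term it called 3778.

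The second comparison asked which transcripts changed when Y14 was reduced. RBM8A was listed at 0 in every arm of both authors' deposited tables, so the knockdown could not be checked. Pooling of both siRNAs in the table left each siRNA's own changes out of reach. IL33, a cytokine of epithelial cells, fell from 3148 ± 80.6 (SD, n = 2) normalised counts to 1115 ± 104 (SD, n = 4) in the recovered libraries. The colon differentiation keratin KRT20 fell from 95.3 ± 9.35 (SD, n = 2) to 22.0 ± 8.83 (SD, n = 4). ARMC5 rose from 394 ± 9.33 (SD, n = 2) to 1145 ± 279.8 (SD, n = 4). ZFAS1, a small nucleolar RNA host transcript, rose from 9821 to 35537 in the authors' deposited table, with an adjusted p of 0.0451.

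The other large increases were C1orf63 at 1.73 and the trafficking complex subunit TRAPPC5 at 1.62 on the log2 scale in the authors' deposited table, and the small nucleolar RNA host SNHG15 with a 2.83-fold change. NME3, a nucleoside diphosphate kinase, had 1.40, ZNHIT2 had 1.38 and GPX1, a glutathione peroxidase, had 1.37 in the authors' deposited table. WDR83 rose from 461 ± 6.30 (SD, n = 2) to 1130 ± 330 (SD, n = 4) normalised counts in the recovered libraries. The glutamate transporter SLC1A3 had 1.25 in the authors' deposited table. Among the other decreases, TMEM170B had -1.58, FRMD3 had -1.57 and F3, the coagulation tissue factor, had -1.55 in the authors' deposited table. ZDHHC21, a palmitoyltransferase, had a ratio of 0.354, and LANCL1 had -1.47 and the long non-coding RNA UCA1 had -1.46 in the authors' deposited table. FAM8A1 had -1.43 and the thrombin receptor F2R had -1.38 in the authors' deposited table. SOX9 had a log2 fold change of -0.20 with an adjusted p of 0.545 in the authors' deposited table. In the recovered libraries LANCL1 had a limma-voom adjusted p of 0.101, with a standard deviation of 982 around its siY14 mean of 1824. Every other gene named among these changes with recovered reads also passed in limma-voom. Separation of the libraries could not be checked for ZFAS1, C1orf63, SNHG15, GPX1, SLC1A3, F3 and FAM8A1.

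The authors' deposited table called 1622 of 17706 genes, 675 higher and 947 lower with siY14. Of these, 109 higher and 160 lower genes changed at least 2-fold in the authors' deposited table. In all 859 called genes with recovered reads, the siY14 and siCtrl libraries did not overlap. The same held for 57.3% of all recovered genes with a mean of at least 10. Chance gives 13.3% for independent libraries but up to 66.7% for libraries in tight pairs, as these were, so this share was not above what chance allows. A limma-voom test of the recovered counts called 1338 of 7300 genes, 593 higher and 745 lower, and 749 of the 850 authors' calls it tested. The balance turned with pseudocounts of 0.1, 1 and 10, at 791, 787 and 766 higher and 721, 721 and 732 lower. With RLE factors 715 were higher and 724 lower. The authors' deposited table held the 4 siY14 libraries as 1 arm, with no column for pairs, so its p-values can be too small. The limma-voom model, and each standard deviation with n = 4, likewise took these 4 libraries as independent, although they formed pairs. With either siCtrl library left out it called 1 gene, while 1317 and 1480 genes had an unadjusted p under 0.05. The spread then came from the siY14 libraries alone, and the lone siCtrl library was assumed to vary like them. The called genes still tested kept their sign, with a median absolute log2 fold change of 0.62 in full and 0.62 and 0.63 without siCtrl library a and b, while the median SE went from 0.12 to 0.18 and 0.17.

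Of the 25 lists tested for siY14, 3 passed cameraPR. G2/M genes, which act in mitosis, were lower with an adjusted p of 8.39e-05 in cameraPR, and 7 of 37 fell and 0 rose, or 11 fell when adjusted over the list alone. The mitotic kinesins KIF11 and CENPE fell by 1.06 and 0.95, the spindle protein PRC1 by 0.75 and the checkpoint kinase BUB1 by 0.70 on the log2 scale in the authors' deposited table. Enterocyte and colonocyte markers were lower with an adjusted p of 2.42e-04 in cameraPR. Of 14 members 7 fell and 0 rose, or 8 fell and 1 rose when adjusted over the list alone. Beside KRT20, the galectin LGALS4 fell by 1.75, the cadherin CDH17 by 0.67 and the transcription factor KLF5 by 0.56 on the log2 scale in the authors' deposited table. The list had an adjusted p = 0.672 with an estimated correlation in camera, over 9 members. Cytosolic ribosomal protein genes were higher with an adjusted p of 0.00119 in cameraPR, and 6 of 47 rose and 0 fell, or 7 rose when adjusted over the list alone. RPLP1 rose by 0.67, RPL28 by 0.62 and RPS19 by 0.52 on the log2 scale in the authors' deposited table. Ribosomal protein genes have processed copies that share reads, so these values are uncertain. G2/M and ribosomal protein genes had too few members with recovered reads for an estimated correlation.

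**Figure D2:**
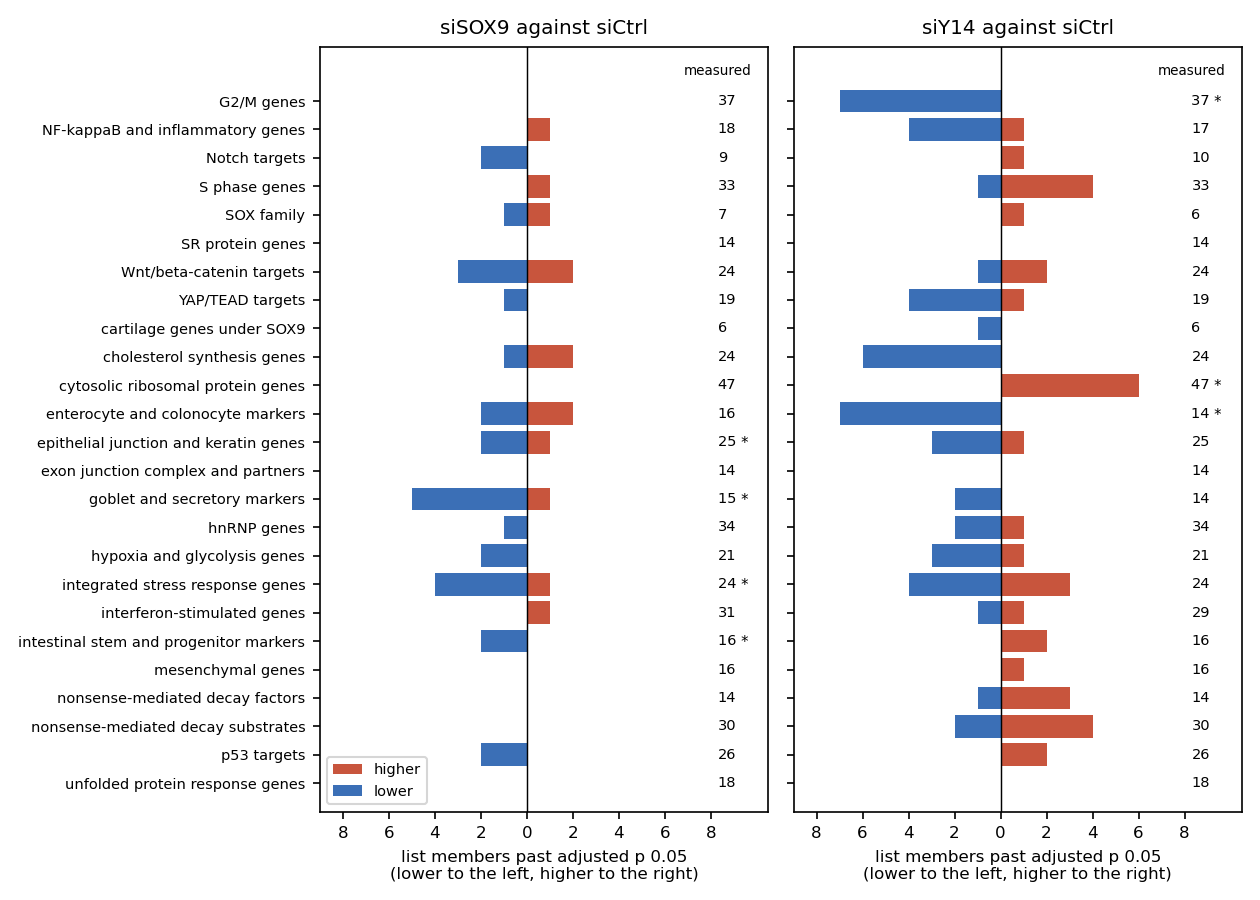
Number of members of each gene list that passed an adjusted p of 0.05 in the authors' deposited table, lower to the left and higher to the right, for siSOX9 and siY14, with the measured members at the right edge and an asterisk where the list passed cameraPR. The asterisks stand at 4 lists for siSOX9 and 3 for siY14.

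Cholesterol synthesis genes had an adjusted p of 0.0565 in cameraPR, with 6 of 24 lower and 0 higher, or 6 and 1 when adjusted over the list alone. INSIG1 fell by 0.99 and HSD17B7 by 0.68 on the log2 scale in the authors' deposited table. Nonsense-mediated decay substrates, transcripts known to rise when that pathway fails, had an adjusted p of 0.0587 in cameraPR, 0.0180 in its rank form and 0.0792 with a GC and length trend removed. On the 7 members with recovered reads, fry gave an adjusted p of 0.00555, and camera gave 0.481 with the preset correlation and an adjusted p = 0.672 with an estimated correlation. Of their 30 members 4 rose and 2 fell, or 6 and 3 when adjusted over the list alone, with SNHG15 higher and the asparagine synthetase gene ASNS lower, at -1.02 in the authors' deposited table. Of 14 nonsense-mediated decay factors 3 rose and 1 fell, or 5 and 3 when adjusted over the list alone, with the helicase DHX34 at 0.94 and PNRC2 at -0.72 in the authors' deposited table. None of 14 exon junction complex genes, 14 SR protein genes or 18 unfolded protein response genes passed in the authors' deposited table. Of 34 hnRNP genes 1 rose and 2 fell, or 2 and 4 when adjusted over the list alone, with MBNL2 at -0.73 and HNRNPA3 at -0.62 on the log2 scale in the authors' deposited table.

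Of 16 stem and progenitor markers 2 rose, or 3 when adjusted over the list alone, the receptor regulator LRIG1 by 1.25 and TERT by 0.96 in the authors' deposited table, and the list had an adjusted p of 0.0832 in cameraPR. Of 14 goblet and secretory markers 2 fell, REG4 by 1.62 and AGR2 by 0.54 on the log2 scale in the authors' deposited table. Of 25 epithelial junction and keratin genes 1 rose and 3 fell, or 1 and 4 when adjusted over the list alone, with the desmosomal genes PKP3 at 0.65 and DSC2 at -0.88 in the authors' deposited table. Of 19 YAP/TEAD targets 1 rose and 4 fell, with TEAD1 at -0.59 in the authors' deposited table. Of 21 hypoxia and glycolysis genes 1 rose and 3 fell, with BNIP3L at -0.97 and HK2 at -0.60 in the authors' deposited table. Of 24 integrated stress response genes 3 rose and 4 fell, or 3 and 5 when adjusted over the list alone, with DDIT4 at -0.99 in the authors' deposited table. Of 17 NF-kappaB and inflammatory genes 1 rose and 4 fell, or 2 and 4 when adjusted over the list alone, with ICAM1 at 0.80 and BIRC3 at -0.86 in the authors' deposited table. Of 33 S phase genes 4 rose and 1 fell, with E2F1 at 0.93 and POLD1 at 0.80 in the authors' deposited table. Of 26 p53 targets 2 rose, AEN by 0.64 and PLK3 by 0.88 in the authors' deposited table.

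Of 29 interferon-stimulated genes ISG15 rose by 1.11 and IFIT1 fell by 1.28 on the log2 scale in the authors' deposited table. Of 24 Wnt/beta-catenin targets 2 rose and 1 fell, with SP5 at 0.76 and TCF7 at -0.56 in the authors' deposited table. NOTCH1 was the called gene of 10 Notch targets, SOX12 of 6 SOX family genes and TAGLN of 16 mesenchymal genes, at 0.60, 0.66 and 0.78 in the authors' deposited table, and 2 SOX family genes rose when adjusted over the list alone. MATN3 was the called gene of 6 cartilage genes, at -1.26 in the authors' deposited table, with a limma-voom adjusted p of 0.0530 in the recovered counts. Of markers of other cell types, 0 of 4 immune and 0 of 3 fibroblast and endothelial genes passed in the authors' deposited table. Apart from the 3 lists past the test, cholesterol synthesis genes and nonsense-mediated decay substrates, all tested lists had adjusted p of 0.0832 to 0.646 in cameraPR.

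Fold changes with siY14 followed the GC content of the genes, with a Spearman correlation of 0.54 across 11045 genes, against -0.07 across 11267 genes for siSOX9. Genes are not independent replicates, and these values describe the tables. Among genes with a mean of at least 100, those called higher had a median GC content of 61.3% and those called lower 41.4%. With a trend in GC content and length removed, cameraPR gave adjusted p of 8.39e-04 for G2/M genes, 1.60e-04 for enterocyte markers and 0.0150 for ribosomal protein genes. Goblet, epithelial, cholesterol, hypoxia and integrated stress response genes then also passed, all lower, with adjusted p of 0.00568, 0.00716, 0.00568, 0.0150 and 0.0278 in cameraPR. In camera on members with recovered reads, without that trend removed, the first 4 of these had adjusted p = 0.695, 0.827, 0.672 and 0.739 with an estimated correlation, and the integrated stress response list leaned higher, with an adjusted p = 0.739 with an estimated correlation. The 4 siY14 libraries formed pairs, a with c and b with d, correlating at 0.997 and 0.996 across 5105 genes, and at 0.932 to 0.933 between libraries of different pairs.

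**Figure D3:**
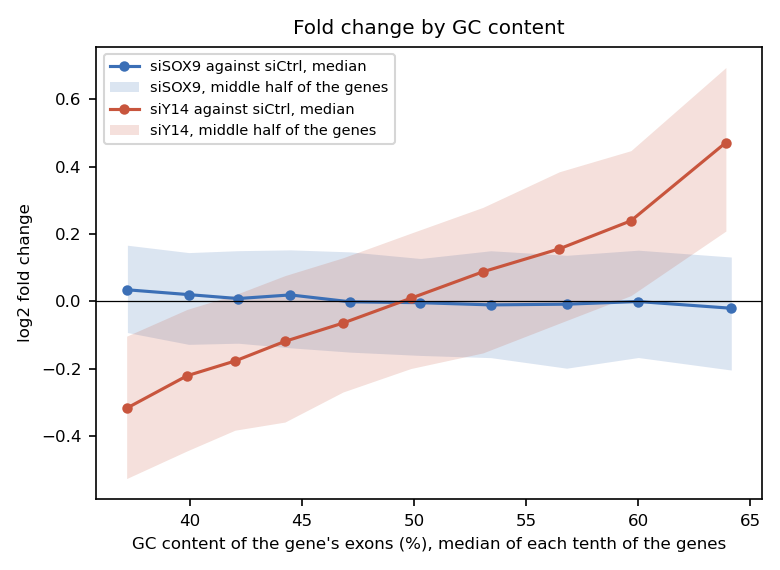
Median log2 fold change (line) and interquartile range (band) of genes with a mean of at least 100, in 10 bins of equal size by GC content in percent, for siSOX9 and siY14 against siCtrl. The siY14 medians ran from -0.32 in the bin of lowest GC content to 0.47 in the highest, and the siSOX9 medians from 0.03 to -0.02.

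The third comparison asked whether the same genes changed with both knockdowns, which shared no library. Of the genes lower in both, the saposin-like gene PSAPL1 had log2 fold changes of -2.03 with siSOX9 and -1.62 with siY14 in the authors' deposited tables. The sulfotransferase SULT1C3 had -1.19 and -1.76, and the serine proteases TMPRSS4 and TMPRSS3 had -1.12 and -1.37 with siSOX9 and -1.99 and -1.09 with siY14 in the authors' deposited tables. KRT20 moved apart, at 1.15 with siSOX9 and -2.12 with siY14, as did SESN3 at 1.54 and -1.32 and GPR137C at 1.12 and -1.27 in the authors' deposited tables. SULF2, an extracellular sulfatase, the corepressor gene HR and the glucose transporter SLC2A12 were lower in both, at -1.40, -1.73 and -1.39 with siSOX9 and at -1.46, -1.23 and -1.11 with siY14 in the authors' deposited tables. In limma-voom on the recovered counts PSAPL1 and SESN3 had siY14 adjusted p of 0.0579 and 0.0625. For TMPRSS4, 1 siSOX9 library stood below the others. Of these genes called in both, SESN3 alone had a mean of at least 5 CPM in both of the authors' deposited tables. PSAPL1 had overall means of 45.7 and 47.9 normalised counts, and SULF2 had 32.4 and 34.0.

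Of 17291 genes tested in both of the authors' deposited tables, 96 were called in both, 57 in the same direction and 39 in opposite directions. Genes lower in both numbered 49 where independent lists of these sizes give 23.2, with a 2-sided Fisher's exact p of 7.28e-07. With genes matched on mean count, 31.1 were expected and a permutation test gave p = 8.0e-04. All overlap tests here take genes as independent draws. Genes that move together can make their p-values too small. Limma-voom calls from recovered counts gave 98 where 63.9 were expected (Fisher's exact p = 8.01e-06). Without siY14 library b they gave 36 where 26.9 were expected (Fisher's exact p = 0.0774) and without library d 30 where 21.3 were expected (Fisher's exact p = 0.0486). Genes higher in both numbered 8 where 8.74 were expected (Fisher's exact p = 1.0), and on recovered counts 24 where 42.2 were expected (Fisher's exact p = 0.00144). That shortfall did not pass with the GC and length trend removed, at 49 where 53.3 were expected (Fisher's exact p = 0.546), or without the filter on the mean (Fisher's exact p = 0.0971). It did not pass without siCtrl library a of the siSOX9 table (Fisher's exact p = 0.0929), or without siY14 library b or d (Fisher's exact p = 0.352 and 0.720). Genes higher with siSOX9 and lower with siY14 numbered 20 where 12.2 were expected (Fisher's exact p = 0.0360), and a level-matched permutation gave p = 0.0859. With p adjusted over genes with a mean of at least 10 they numbered 27 where 18.2 were expected (Fisher's exact p = 0.0353), and a level-matched permutation gave p = 0.0155. Recovered counts gave 44 where 53.4 were expected (Fisher's exact p = 0.176). Genes lower with siSOX9 and higher with siY14 numbered 19 where 16.6 were expected (Fisher's exact p = 0.526), and on recovered counts 45 where 50.5 were expected (Fisher's exact p = 0.441). With depth class as a term for siSOX9, 296 genes were called in the same direction and 323 in opposite directions, and those lower with siSOX9 and higher with siY14 numbered 153 where 123.4 were expected (Fisher's exact p = 0.00189). The direction of this departure depended on the setting. Without the filter on the mean they numbered 24 where 15.9 were expected (Fisher's exact p = 0.0484). With TMM factors they numbered 35 where 53.6 were expected (Fisher's exact p = 0.00427), with RLE factors 40 where 60.6 were expected (Fisher's exact p = 0.00279), and with the pseudocounts Fisher's exact p was 0.02001 to 0.0286, also below the expected number. Across 11069 genes with a mean of at least 100 in both tables, the log2 fold changes had a Pearson correlation of 0.07 and a Spearman correlation of 0.06. Across 7662 genes with a mean of at least 1000 these were 0.03 and 0.01.

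**Figure D4:**
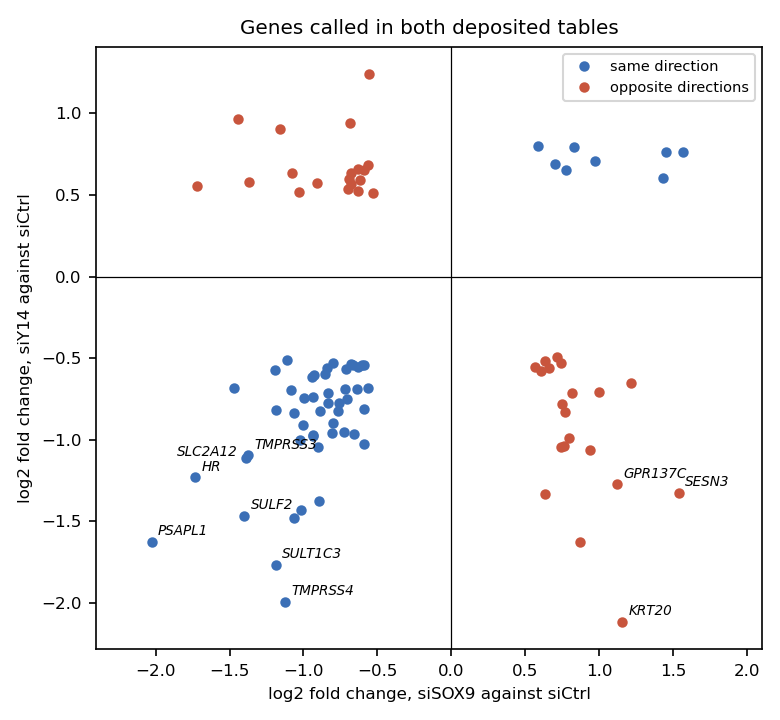
Log2 fold change with siY14 against that with siSOX9 for the 96 genes called in both of the authors' deposited tables, with 1 point per gene and the named genes marked. The lower left part holds 49 genes and the upper right 8.

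The difference between the knockdowns was tested in a joint limma-voom model of 7101 genes with recovered reads in both tables. It called 1206, of which 640 were relatively higher with siSOX9 and 566 relatively higher with siY14. That model took the 4 siY14 libraries as independent, although they formed pairs, so its errors and p-values can be too small. DACT1 differed by 3.36 ± 0.30 (SE) on the log2 scale and MANSC4 by 4.79 ± 0.45 (SE), each higher with siSOX9. IL33 differed by 1.73 ± 0.15 (SE), PARP8, an ADP-ribosyltransferase, by 1.55 ± 0.14 (SE) and SGPP1, a sphingosine-1-phosphate phosphatase, by 1.30 ± 0.11 (SE), each lower with siY14. The trypsinogen gene PRSS1 differed by -3.02 ± 0.25 (SE) and ITPRIP by -1.29 ± 0.12 (SE). These 7 genes had a limma-voom adjusted p of 2.98e-05. With siCtrl, IL33 stood at 1254 normalised counts in the siSOX9 table and 3148 in the siY14 table, which were scaled separately. SGPP1 stood at 1646 and 3015, and PARP8 at 1186 and 1309. The tables came from different experiments, so differences between the knockdowns cannot be told apart from differences between experiments. TERT differed by -2.37 ± 0.24 (SE) with a limma-voom adjusted p of 5.59e-05, and PSD4 by -1.15 ± 0.12 (SE) with 5.00e-05. TERT and PRSS1 fell with siSOX9 and rose with siY14 in limma-voom, at -1.43 and 0.94 for TERT and -2.31 and 0.72 for PRSS1. KRT20 and SESN3, chosen after their values were seen, differed by 3.29 ± 0.31 (SE) and 3.01 ± 0.45 (SE), with limma-voom adjusted p of 3.34e-05 and 8.63e-04. Without siCtrl library a or b of the siY14 table, limma-voom called 353 and 439 differences. The lone siCtrl library was then assumed to vary like the other groups, and the 1206 differences kept their sign, with a median absolute size of 0.91 in each case.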

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

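The tests of the paired siY14 libraries and of experiment 2 as a batch were chosen after the result was seen, as was the use of recovered counts. Of 86 named or family genes with recovered reads in the 4 siSOX9 libraries, 5 had 1 library far from the other 3. Chance gives about 1 in 20 such genes for independent libraries. The siY14 libraries, being paired, leave little room for 1 to stand apart.

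ANKRD27 stood at 1806 normalised counts in siSOX9 library a, against 1390 to 1447 in the other siSOX9 libraries. HIST1H2BF stood at 13.4 in the same library, against 32.1 to 35.2. CREB3L1 stood at 12.4 in siSOX9 library b, against 2.52 to 4.14. TMPRSS4 stood at 39.4 and SULT1C4 at 18.6 in siSOX9 library d, against 46.1 to 47.2 and 40.4 to 44.5.

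The deepest siCtrl library and the deepest siSOX9 library of the siSOX9 table stood apart from the rest in the same genes. The correlation of their deviations from the arm means was 0.88 across 5770 genes, and the highest between other libraries of different arms was 0.62. After thinning to the depth of the shallowest library it was 0.82. Thinning keeps each gene's expected normalised count and only adds noise, so it cannot decide whether read depth was the cause. A batch shared by the 2 libraries, such as experiment 2, could give the pattern, but 0 libraries carry an experiment name, so this cannot be told apart from other causes. No biological explanation was tested.

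The 4 siY14 libraries formed 2 pairs, and each pair held a deeper and a shallower library. The lowest correlation within a pair exceeded the highest between libraries of like depth by 0.0623, which argues against sequencing depth. The 2 siRNAs could account for the pairs, but 0 libraries carry the name of their siRNA, so this explanation cannot be told apart from a split by preparation.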

How the results depend on the processing

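The alternatives on recovered counts other than leaving out libraries, the mean filter, TMM and RLE factors, pseudocounts and the list tests were chosen after the result was seen. With at least 2-fold change, 265 siSOX9 and 269 siY14 genes were called, and 12 in both. On recovered counts limma-voom called 1414 siSOX9 genes, 3778 with depth class as a term and 2298 without the deepest libraries, and 935 to 1790 with each library left out in turn (935 without siSOX9 library d). For siY14 this range was 1 to 1720, with 1 call without siCtrl library a or b, where the lone siCtrl library was assumed to vary like the siY14 libraries, 487 without siY14 library b and 373 without d. For the difference it was 353 to 1426, and 1839 with depth class as a term. Genes called in both numbered 211 on recovered counts, 116 without the filter on the mean, 619 with depth class as a term (296 in the same direction and 323 in opposite ones) and 0 to 274 with a library left out. The 0 came without siCtrl library a or b of the siY14 table, where 0 siY14 calls were left to overlap, 80 and 68 without siY14 library b and d, and 138 without siSOX9 library d. Genes lower in both were 1.53 times the expected number on recovered counts, 1.28 times with depth class as a term, and 1.34 to 1.76 times with a library left out, with the call lost without siY14 library b (1.34) and no ratio without either siCtrl library of the siY14 table. Genes higher in both were 0.568 of the expected number on recovered counts (Fisher's exact p = 0.00144), 0.737 with depth class (Fisher's exact p = 2.39e-04) and 0.919 with GC and length removed (Fisher's exact p = 0.546). Lists past the test for siSOX9 numbered 2 with GC and length removed, 2 on recovered counts, with RLE factors and with each pseudocount, 2 with depth class, 0 with an estimated correlation, 8 in fry and 2 to 2 with a library left out. For siY14 they numbered 8 with GC and length removed, 0 on recovered counts, with RLE factors and with each pseudocount, 0 with an estimated correlation, 10 in fry and 0 to 0 with a library left out. Fewer members have recovered reads, and for all other changes the cause was not tested. Fry tests only whether a list moves on balance.

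Directions reversed as follows, and the cause was not tested. Genes higher with siSOX9 and lower with siY14 were 0.824 of the expected number on recovered counts and with TMM factors, 0.856 with RLE factors, 0.817, 0.813 and 0.830 with pseudocounts of 0.1, 1 and 10, and 0.682 to 1.07 with a library left out (above 1 without siY14 library d). This shortfall passed without siSOX9 library a (Fisher's exact p = 0.00222) or siCtrl library b (Fisher's exact p = 0.0344) of the siSOX9 table. Genes lower with siSOX9 and higher with siY14 were 0.860 of the expected number matched on mean count, 0 with at least 2-fold change, 0.803 with p adjusted over genes with a mean of at least 10, 0.890 on recovered counts, 0.813 with GC and length removed, 0.652 with TMM and 0.660 with RLE factors, 0.746, 0.740 and 0.759 with the pseudocounts, and 0.646 to 1.18 with a library left out (above 1 without siY14 library b or d, and Fisher's exact p = 6.46e-04 without a). The integrated stress response list turned higher without siCtrl library c (p 0.980) and without siSOX9 library a (p 0.857) in camera, with a range of 0.701 to 0.980 over the libraries left out. Other lists turned on their 5 to 15 members with recovered reads, and adjusted p are given for the preset correlation, an estimated one, fry, RLE factors and the pseudocounts in that order, then with a library left out. For siSOX9, cholesterol genes turned lower (0.514, 0.703, 0.0255, 0.522, 0.6004, 0.6005 and 0.603, then 0.400 to 0.701) and nonsense-mediated decay substrates higher (0.636, 0.703, 0.197, 0.620, 0.628, 0.631 and 0.640, then 0.608 to 0.753), also with depth class as a term (0.714 and 0.716). For siY14, integrated stress response genes turned higher (0.614, 0.739, 0.00555, 0.544, 0.621, 0.620 and 0.611, then 0.597 to 0.745) and Wnt targets lower (0.881, 0.954, 0.605, 0.850, 0.840, 0.841 and 0.848, then 0.568 to 0.990 and lower in 3 of 6). YAP/TEAD targets turned higher except with RLE factors (0.993, 0.995 and 0.927, with pseudocounts 0.995, 0.995 and 0.999, then 0.689 to 0.990 and higher in 3 of 6). With GC and length removed, SR protein and hnRNP genes turned higher with siY14 (p 0.621 and 0.624), and HES6 had -0.11. The DACT1 log2 fold change, siY14 against siCtrl, was near 0 and had -0.00683 on recovered counts, -0.00689 without the filter on the mean, -0.00835 with the GC and length trend removed, -0.0399 with TMM and -0.0219 with RLE factors, -0.00690, -0.00649 and -0.00366 with the pseudocounts, and -0.13 to 0.0772 with a library left out (-0.08 without siCtrl library b, -0.13 without siY14 library b).

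Of called siSOX9 genes named or in families, 496 values with a library left out kept direction and call, and 8 lost the call, for HIST1H2BF, HIST2H2BC, SULT1C4 and RAB30. All 811 values under other alternatives kept both, but 91 of them came from equal arm totals, which tested direction alone. For siY14 225 kept both and 255 lost the call, and under other alternatives 695 kept both and 96 lost the call. The 695 include 151 from equal arm totals, which tested direction alone. The 10 genes of the difference kept both in all 130 values with a library left out and in 90 others. Of the 35 splits of the 7 siSOX9 table libraries into 3 and 4, 1 gave as many calls, the labelled one with 1414, a share under 0.05, and the highest other gave 1. The 20 splits with 1 of the 2 deepest libraries in each group are too few for a share under 0.05, and the highest other among them gave 0.

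No paired analysis was possible because the columns carry no replicate numbers. Fits per Y14 siRNA, an experiment term and experiment 1 alone were not run, since no recovered library carries a sample name. DESeq2 was not run, since whole reads came out for part of the genes. SOX9 and RBM8A have no recovered reads, so their levels have no value under these alternatives. Depth limits genes near the mean of 10.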

Other observations

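The tests of gene families and of GC content were chosen after fold changes had been seen. Families of genes were taken by symbol, 16 families in each table, giving 32 tests with limma's cameraPR. Narrower symbol patterns without pseudogene and readthrough symbols were added after the first result.

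Polyadenylated transcripts of histone genes with HIST symbols, most of which encode proteins of chromatin, were higher with siSOX9. Of 22 genes 7 were called, with an adjusted p of 4.02e-15 in cameraPR. HIST1H3H rose by 2.94, HIST2H2BE by 1.82 and HIST1H2AC by 1.34 on the log2 scale in the authors' deposited table. HIST1H3H was low with siCtrl, at 12.2 normalised counts against 93.3 with siSOX9. Histone genes share reads with near-identical copies, so the values of single genes are uncertain. The libraries were made from polyadenylated transcripts, so histone transcripts without a poly(A) tail are not measured by these values. The transmembrane serine protease genes TMPRSS2, TMPRSS3 and TMPRSS4 fell with siSOX9, 3 of 6 measured, with an adjusted p of 0.00319 in cameraPR.

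With siY14, small nucleolar RNA host genes had a median log2 fold change of 0.82, and SNHG15, SNHG17 and SNHG11 were the 3 of 12 that rose, with an adjusted p of 1.73e-04 in cameraPR. These transcripts carry small nucleolar RNAs in their introns. Kinesin genes were lower, with 7 of 35 falling and KIF26A rising, and an adjusted p of 0.00992 in cameraPR. KIF14 fell by 0.77 and KIF20B by 0.76 on the log2 scale in the authors' deposited table. The cytosolic sulfotransferase genes SULT1C2, SULT1C3 and SULT2B1 fell, 3 of 5 measured, with an adjusted p of 0.0106 in cameraPR, though SULT2B1 had 0.0699 in limma-voom on recovered counts. Zinc finger genes with ZNF symbols were higher, with 23 of 394 rising and 8 falling, and an adjusted p of 0.00319 in cameraPR. Mitochondrial ribosomal protein genes were higher, with 7 of 79 rising and an adjusted p of 0.0137 in cameraPR. With narrower symbols these became 21 of 375 and 6 of 75, and the latter had an adjusted p of 0.0191, or 0.0611 with a GC and length trend removed.

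Fold changes with siY14 rose with GC content, and the GC slopes split by pair, at 0.0039 and 0.014 log2 per 10% GC for siY14 libraries a and c, 0.15 and 0.16 for b and d, and -0.17 and -0.16 for the siCtrl libraries. A GC and length trend between libraries as the whole cause is argued against, since 57.7% of the calls from recovered counts, 772 of 1338, remained called in the same direction after the trend was removed. Chance variation of the trend cannot be told apart: the GC slopes of the 2 siCtrl libraries differed by 0.0497 of the gap to the nearest siY14 library, but siCtrl slopes in the siSOX9 table ranged over 0.19 log2 per 10% GC, more than that gap of 0.16. A candidate explanation that stays open is a share of exon number, as the partial Spearman correlation with exon number at fixed GC content and length was -0.16, against -0.05 for siSOX9. A batch difference between siCtrl and siY14 libraries, and an effect of Y14 on spliced transcripts, were not tested apart.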
